A study of Mus musculus with 14 samples.

How the data were processed

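Cells were sorted from mouse colon by flow cytometry, per the labels. Lamina propria macrophages were positive for CD45, CD11b, CD64 and MHC class II and negative for Ly6G, SiglecF, CD24, CD103 and Ly6C. Epithelial cells were positive for CD44 and EpCAM and negative for CD45. Full-length cDNA was made with Smart-seq2, which primes on polyadenylated RNA and keeps no strand, and libraries with Nextera XT were sequenced as 50 bp single reads. The submitters' processing notes name STAR 2.5.2b, Picard 2.19.2, DESeq2 1.24.0 and the mouse genome GRCm38. The role of each tool, the read counter, the annotation release and the strand setting are not given in the sources used here. Reads of a gene and of an antisense partner cannot be told apart, and reads of similar paralogs and pseudogenes may be split between them or lost.

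The authors deposited raw counts, whole numbers per gene and library with ribosomal and mitochondrial genes included, and a table of FPKM. The deposited FPKM equalled the count divided by a value per gene and by 1 factor per library, to a relative deviation of 6.66e-16 over 8050 genes. Each table held 14 columns, 1 per library. Group, mouse number and sex were taken from the labels. The titles carry 4 mouse numbers for each genotype, whereas the series text states 3 control and 4 cre mice. If the text is right, 2 wt epithelial libraries could share an animal, and p-values would be too small. No 2 columns of a group were copies of each other (smallest chi-square per degree of freedom 6.72, for wt epithelial 2 and 4), which does not show whether 2 libraries share an animal. Xist and Y-linked genes matched the labelled sex in 14 of 14 libraries.

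Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr at a minimum count of 10, the robust quasi-likelihood F test and a Benjamini-Hochberg adjusted p under 0.05. Each cell type was fitted alone on genotype. The difference of genotype effects and the difference between cell types were fitted on all 14 libraries with 4 groups, the latter also requiring an absolute log2 fold change of 1. SE is the size of the log2 change divided by the square root of the F statistic, and CPM are counts scaled to the TMM library size. An exact permutation test of 1 value in 3 against 3 libraries cannot give a two-sided p below 0.10, and in 4 against 4 none below 0.0286. Lists were tested with camera from limma 3.58.1 with an inter-gene correlation preset to 0.01, then with an estimated correlation and with fry. The 45 lists covered metabolism, stress, lysosome, cell cycle, and genes of macrophages, other immune cells, epithelium and stroma. Atp5f1, H2afz and Sept3 did not match a symbol, 114 symbols held by more than 1 row were left out of lists, and a list needed 5 measured members. Lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were Tsc2 and Lyz2; the 8 largest rises and 8 largest falls past the threshold with a mean of 5 CPM, without sex-linked genes, antibody and T cell receptor segments and provisional names; the 4 members with the smallest p of each list that passed; and the 5 smallest p for the difference of effects. In epithelial cells 1 gene that this rule takes is not reported here and was not replaced.

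Alternatives were RLE size factors, DESeq2 1.42.0, no filter, a filter of 50 counts, voom with quality weights, and limma on log2(FPKM + 1) with a mean FPKM of 1 or more, with a pseudocount of 0.1 or without that filter. Sex as a covariate, males only, all libraries in one fit, a block on mouse number and leaving out each library were also run. Chosen after seeing the data were 4 alternatives: a spline trend of expression on GC content and transcript length (5 degrees of freedom each) removed in each library, the ribosomal RNA share as a covariate, ribosomal, mitochondrial and pseudogene rows left out, and 2 libraries left out at once. GC content and length came from GENCODE M21, and 99.9% of genes tested had both. Models were tested on simulated data with known 2-fold and 4-fold changes. In macrophages 19.4% of 2-fold and 72.4% of 4-fold changes were recovered, and in epithelial cells 67.0% and 98.0%. For the difference of effects the shares were 12.0% and 61.0%, and between cell types 74.0% and 96.0%. DESeq2 called 35 unchanged genes in simulated macrophages and edgeR 10. A simulated GC trend gave 3938 calls in epithelial cells, and 1 after its removal. Intervals are 95% and, like floors, cover counting error only, since PCR copies are not independent molecules.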

Results

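RNA was sequenced from 14 libraries of cells sorted from mouse colon. Control animals carried floxed Tsc2 and no recombinase (wt). The others also carried Cre recombinase in the Lyz2 locus, which is active in myeloid cells (cre). Tsc2 encodes tuberin, a subunit of the complex that restrains the growth-promoting kinase complex mTORC1. Lamina propria macrophages gave 3 cre and 3 wt libraries, and CD44+ EpCAM+ epithelial cells gave 4 cre and 4 wt libraries. Each library held between 7269103 and 9364551 counts over 55487 genes. All 3 cre macrophage libraries came from males, against 1 male and 2 females for wt. The cre epithelial libraries came from 3 males and 1 female, and the wt ones from 2 males and 2 females. The comparisons ask what accompanies deletion of Tsc2 in Lyz2-expressing cells, first in the macrophages and then in the epithelium beside them. No group carried the recombinase without floxed Tsc2, so the deletion and the recombinase allele always go together.

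The sorted populations were distinct. Epcam, an epithelial adhesion molecule, stood at 485 ± 77.7 CPM (SD, n = 8) in epithelial and 7.74 ± 4.74 CPM (SD, n = 6) in macrophage libraries. The mucin gene Muc2 stood at 3396 ± 844 CPM (SD, n = 8) and 27.4 ± 17.1 CPM (SD, n = 6). Csf1r, the receptor for a macrophage survival factor, stood at 1812 ± 254 CPM (SD, n = 6) in macrophages and 7.95 ± 4.82 CPM (SD, n = 8) in epithelial libraries. All 19 pan-epithelial markers and 23 of 24 goblet cell genes were higher in epithelial cells. All 26 genes of the resident gut macrophage list were higher in macrophages. The 19 fibroblast and smooth muscle markers and the 16 B and plasma cell markers measured were also higher in macrophage libraries, with median log2 differences of 9.07 and 6.27. Of 16375 genes tested with edgeR, 8543 differed by at least 2-fold with an adjusted p under 0.05. Of these, 4861 were higher in macrophages and 3682 in epithelial cells.

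Tsc2 (ENSMUSG00000002496, chromosome 17, 24595816 to 24632630, GRCm38) did not pass the test in either population. In macrophages it stood at 31.3 ± 7.46 CPM in wt and 28.3 ± 3.98 in cre (SD, n = 3 each). The log2 change was -0.14 (SE 0.23, edgeR adjusted p = 0.860), and it turned to 0.31 with sex in the model and to 0.32 in males alone. For Tsc2 in macrophages it was -0.33 without wt 6, -0.24 without cre 9, -0.04 without cre 10, -0.08 without wt 4 and -0.01 without wt 2. In epithelial cells Tsc2 stood at 52.0 ± 2.72 CPM in wt and 57.5 ± 3.66 in cre (SD, n = 4 each; log2 change 0.14, SE 0.11, edgeR adjusted p = 0.414). A count over the whole gene includes exons outside a floxed segment, so it is a weak check of the deletion. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321) encodes lysozyme and holds the recombinase. In macrophages it stood at 7302 ± 876 CPM in wt and 6278 ± 164 in cre (SD, n = 3 each; log2 change -0.22, SE 0.15, edgeR adjusted p = 0.634). Reads can be shared between Lyz2 and the similar gene Lyz1.

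By camera with the preset correlation, the lists of lysosomal and lipid handling genes were higher in cre macrophages, and those of dendritic cell and MHC class II genes lower. With an estimated correlation the adjusted p was 0.0250 for lipid handling and for dendritic cell genes, which passed, and 0.0847 for lysosomal and for MHC class II genes, which did not. The estimates were -0.037 for lipid handling and -0.0015 for dendritic cell genes, both below the preset 0.01. They were 0.260 for lysosomal and 0.031 for MHC class II genes. Gpnmb, a lysosome-associated glycoprotein of lipid-laden macrophages, rose from 12.4 ± 1.87 to 2291 ± 719 CPM (SD, n = 3 each). Its log2 change was 7.53 (SE 0.30, edgeR adjusted p = 1.66e-05). Atp6v0d2, a subunit of the lysosomal proton pump, rose by 6.25 on the log2 scale (SE 0.83, adjusted p = 0.0359). The fatty acid binding protein gene Fabp5 rose by 4.20 (SE 0.27) and Syngr1 by 3.97 (SE 0.29). Mmp27, a matrix metalloproteinase gene, had no count in wt and 10.2 ± 0.854 CPM in cre (SD, n = 3). That is at least 29.0-fold higher, against a floor of 3 counts per wt library. Rises also occurred in Klra3 (3.74, SE 0.50), Cd200r4 (3.30, SE 0.49) and the protease gene Ctsd (2.83, SE 0.23). Klra3 and Cd200r4 belong to families of similar genes that can share reads. Among genes past the threshold with a mean of at least 5 CPM, the largest falls were in Vipr2, a receptor for a gut neuropeptide (-2.72, SE 0.31), Mfap4 (-2.11, SE 0.30), Itgae (-2.09, SE 0.28) and Pde1b (-2.03, SE 0.26). Tlr11, a sensor of microbial protein (-1.98, SE 0.32), C1qtnf3 (-1.97, SE 0.32), Mmp23 (-1.96, SE 0.31) and the matrix gene Fbln1 (-1.91, SE 0.33) fell too. Itgae encodes CD103, an antigen that the sort gate excluded.

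In all, 133 of 14087 genes changed, 103 higher and 30 lower in cre. The genes changed by genotype in macrophages numbered 2 with sex in the model, 32 in males alone and 517 with DESeq2. Single libraries moved the count too: it was 29 without cre 10, 44 without cre 8, 87 without cre 9, 41 without wt 2, 35 without wt 4 and 62 without wt 6. Among the named genes, 18 lost their call without cre 10, 13 without cre 8, 9 without cre 9, 11 without wt 2, 15 without wt 4 and 8 without wt 6.

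**Figure D1:**
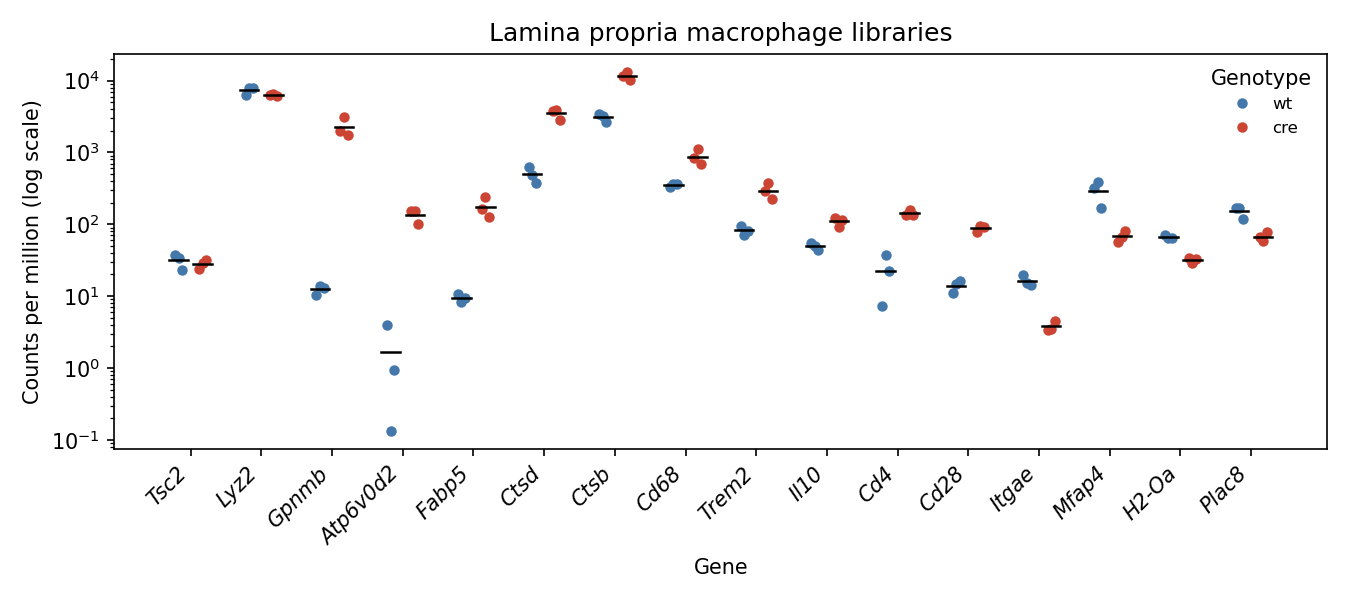
CPM (log axis) of 16 genes in the macrophage libraries; each point is 1 library (3 wt in blue, 3 cre in red) and each bar a group mean. Gpnmb averaged 12.4 CPM in wt and 2291 CPM in cre, and Tsc2 31.3 and 28.3 CPM.

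By camera with the preset correlation, the lysosome list had the lowest p of the 44 lists tested in macrophages. All 39 measured members had a positive log2 change, with a median of 0.68. Of these, 12 rose among all genes and 32 rose adjusted over the list alone (camera adjusted p = 4.04e-42; adjusted p = 0.0847 with an estimated correlation). Besides Gpnmb and Ctsd, the cathepsin gene Ctsb rose from 3105 ± 415 to 11686 ± 1495 CPM (SD, n = 3 each; log2 change 1.91, edgeR adjusted p = 0.00206). Cd68, a lysosomal membrane protein of macrophages, rose from 353 ± 19.4 to 872 ± 211 CPM (SD, n = 3 each; log2 change 1.31, edgeR adjusted p = 0.0220). Of 23 lipid handling genes, 3 rose among all genes and 8 rose adjusted over the list alone (camera adjusted p = 2.06e-15; adjusted p = 0.0250 with an estimated correlation). The 3 were Gpnmb, Fabp5 and the lipid-sensing receptor gene Trem2 (log2 change 1.85, SE 0.22). Plin2, a lipid droplet coat protein, had a log2 change of 1.08 that did not pass (adjusted p = 0.0770).

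Further lists were higher in cre macrophages by camera with few single genes past the threshold. Of 27 inflammatory cytokines and chemokines, Ccl8 rose (1.62, SE 0.29) and 4 rose adjusted over the list alone. Cxcl1, Cxcl3 and Cxcl2 had log2 changes of 1.13, 0.94 and 0.69 that did not pass. The list had a camera adjusted p = 0.00580 (adjusted p = 0.489 with an estimated correlation), and 0.0616 with sex in the model and 0.0862 without wt 2. Of 31 macrophage growth factors 2 rose, and 6 rose and 1 fell adjusted over the list alone. These were Grn, which encodes the lysosomal precursor progranulin (1.27, SE 0.16), and the anti-inflammatory cytokine gene Il10 (1.16, SE 0.17). Igf1 (0.74) and Mmp12 (-0.99) did not pass. This list had a camera adjusted p = 0.0307 (adjusted p = 0.267 with an estimated correlation). Its call was lost with sex in the model (0.1704) and without cre 10 (0.106), cre 9 (0.0652) or wt 6 (0.0530). Of 26 resident gut macrophage genes only Il10 rose, and 7 rose and 3 fell adjusted over the list alone. Cd4 (2.68, SE 0.52), Itgax (-0.71) and Lyve1 (-1.22) did not pass. For these 26 genes the camera adjusted p was 0.0101 (adjusted p = 0.872 with an estimated correlation), and 0.494 with sex in the model and 0.246 without wt 2. Of 30 autophagy genes none passed among all genes and 3 rose adjusted over the list alone (camera adjusted p = 0.00853; adjusted p = 0.201 with an estimated correlation). Tecpr1, Rragd, Optn and Fnip1 had log2 changes of 1.52, 2.95, 1.26 and 0.67. The estimated correlation of the autophagy list was -0.000332, below the preset 0.01, so a larger correlation did not cost it the call. Of 42 interferon response genes none passed in either way (camera adjusted p = 0.0475; adjusted p = 0.872 with an estimated correlation). Oas2, Dhx58, Gbp6 and Ifi204 had log2 changes of 1.38, 0.48, 1.60 and 0.55. That call was lost without cre 9 (0.653), wt 2 (0.0745) or wt 6 (0.255).

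Dendritic cell markers were lower in cre macrophages, with negative log2 changes in 19 of 19. Itgae fell, and 15 fell adjusted over the list alone (camera adjusted p = 2.78e-13; adjusted p = 0.0250 with an estimated correlation). Dpp4 (-1.39), Xcr1 (-1.26) and Naaa (-0.75) did not pass. Of 15 genes of antigen presentation by MHC class II, H2-Oa fell (-1.05, SE 0.16) and 10 fell adjusted over the list alone (camera adjusted p = 8.06e-08; adjusted p = 0.0847 with an estimated correlation). H2-Ob, H2-DMa and Cd74 had log2 changes of -0.72, -0.61 and -0.72. Of 19 fibroblast and smooth muscle markers, 13 had a negative and 6 a positive log2 change, none passed among all genes and 7 fell adjusted over the list alone (camera adjusted p = 1.87e-06; adjusted p = 0.489 with an estimated correlation). Those with the smallest p, Dpt, Postn, Lum and Dcn, had log2 changes of -1.17, -1.13, -1.54 and -1.32. Transcripts of these cells were present in both genotypes, with Dcn at 809 ± 220 CPM in wt and 325 ± 123 in cre (SD, n = 3 each). The call of that list was lost without cre 8 and wt 2 together (0.0522). Of 6 eosinophil and mast cell genes none passed among all genes and 4 fell adjusted over the list alone (camera adjusted p = 0.000114; adjusted p = 0.212 with an estimated correlation). Ear2, Alox15, Siglecf and Ccr3 had log2 changes of -0.97, -1.25, -1.44 and -0.71.

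Of 15 T cell and innate lymphoid genes, Cd28 rose although the list was lower (camera adjusted p = 0.0167; adjusted p = 0.236 with an estimated correlation). The list call was lost without cre 9 (0.0741) or wt 6 (0.0833). Cd28 went from 14.04 ± 2.65 to 88.0 ± 8.79 CPM (SD, n = 3 each; log2 change 2.65, SE 0.20), and 1 rose and 4 fell adjusted over the list alone. Cd8a, Nkg7 and Cd3g, at 1.82, 5.04 and 3.35 CPM in wt, had log2 changes of -4.93, -1.60 and -2.03. Of 16 monocyte genes Plac8 fell (-1.17, SE 0.19), also adjusted over the list alone. Ccr2 (-0.79), Treml4 (-0.61) and S100a4 (-0.55) did not pass. Camera gave the monocyte list an adjusted p = 0.0168 (adjusted p = 0.572 with an estimated correlation), and 0.253 without cre 8 and 0.0777 without wt 6. Of 71 cytosolic ribosomal protein genes none passed in either way (camera adjusted p = 0.0167; adjusted p = 0.897 with an estimated correlation). Rps18, Rps23, Rps6 and Rps25 had log2 changes of -0.53, -0.50, -0.35 and -0.43. That call was lost without cre 10 (0.162), cre 9 (0.616) or wt 6 (0.142). In all 14 lists passed, 7 higher and 7 lower, and 9 did so without wt 6. With an estimated correlation 2 passed, lipid handling and dendritic cell, and fry called 8. Other groupings of the 6 libraries gave up to 17 lists.

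In epithelial cells of cre mice many genes changed by small amounts. By camera with the preset correlation, the lists with the lowest p were oxidative phosphorylation, glycolysis and the ATF4 response, which were higher, and stem cell and Wnt target genes, which were lower. With an estimated correlation no list passed, with camera adjusted p of 0.672, 0.235, 0.0976 and 0.235 for these. The estimates were 0.247, 0.111, 0.00761 and 0.0512, so that of the ATF4 response lay below the preset 0.01. Among genes with a mean of at least 5 CPM the largest rise was in Akr1c21, an aldo-keto reductase, from 2.08 ± 0.967 to 8.30 ± 1.43 CPM (SD, n = 4 each; log2 change 1.98, SE 0.30, edgeR adjusted p = 0.00648). Rises also occurred in the mitotic transcription factor gene Foxm1 (1.18, SE 0.31), Sh3bgr (1.16, SE 0.23), Ciz1 (1.07, SE 0.31) and Tmem45a (1.05, SE 0.23). Gsta1, a glutathione transferase gene (1.00, SE 0.20), Cyb5d2 (0.99, SE 0.27) and Slc27a3 (0.97, SE 0.26) rose too. The largest fall among genes with a mean of at least 5 CPM was in Hpgd, which inactivates prostaglandins, from 47.7 ± 18.1 to 15.7 ± 3.18 CPM (SD, n = 4 each; log2 change -1.60, SE 0.25, edgeR adjusted p = 0.00701). Ppp3r1 (-1.56, SE 0.25), Laptm5 (-1.43, SE 0.34), H2-Aa (-1.43, SE 0.34) and Miga1 (-1.40, SE 0.30) fell, as did Cybb (-1.33, SE 0.32) and the mitochondrial ribosomal RNA mt-Rnr1 (-1.32, SE 0.25). Laptm5, H2-Aa, Cybb and Lyz2 were at least 6 log2 units higher in macrophages, where each stood at 500 CPM or more. Lyz2 fell from 37.4 ± 10.3 to 14.2 ± 3.26 CPM (SD, n = 4 each; log2 change -1.40, SE 0.21, edgeR adjusted p = 0.00648). For Lyz2 in epithelial cells the log2 change was -1.05 with the ribosomal share in the model (adjusted p = 0.162), which did not pass.

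In all, 1243 of 13553 genes changed, 765 higher and 478 lower. Of these, 17 of the rises and 108 of the falls reached 2-fold. On the deposited FPKM the split was 1142 higher and 246 lower. The ribosomal RNA gene CT010467.1 took 13.3 ± 9.05% of counts in cre and 23.4 ± 5.87% in wt (SD, n = 4 each; exact two-sided permutation p = 0.114, adjusted p = 0.229 over 10 tests of library measures). Mitochondrial genes took 10.5 ± 0.133% and 15.5 ± 2.96% (SD, n = 4 each; exact two-sided permutation p = 0.0286, adjusted p = 0.229). The mitochondrial shares did not overlap, at 10.4 to 10.7% in cre and 11.6 to 18.1% in wt. Their exact permutation p is the smallest that 4 against 4 libraries allow. Since the macrophage tests cannot go below 0.10, no adjusted p over the 10 tests could fall under 0.05. Across genes, which are not independent replicates, the log2 change followed GC content (Spearman rho 0.328) and transcript length (rho -0.373). With that trend removed 577 genes changed, 454 higher and 123 lower, of which 418 were among the 1243. The genes changed by genotype in epithelial cells numbered 0 by edgeR with the ribosomal share in the model (1727 at an unadjusted p under 0.05; DESeq2 without that term called 1967), and 5 in males alone. The count was 178 without cre 9, 318 without cre 5, 548 without cre 10, 682 without wt 2 and 1947 without cre 8. Among named genes, 33 lost their call without cre 9, 27 without cre 5, 15 without cre 10, 11 each without wt 2 and wt 7, 6 each without wt 4 and wt 6, and 1 without cre 8.

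**Figure D2:**
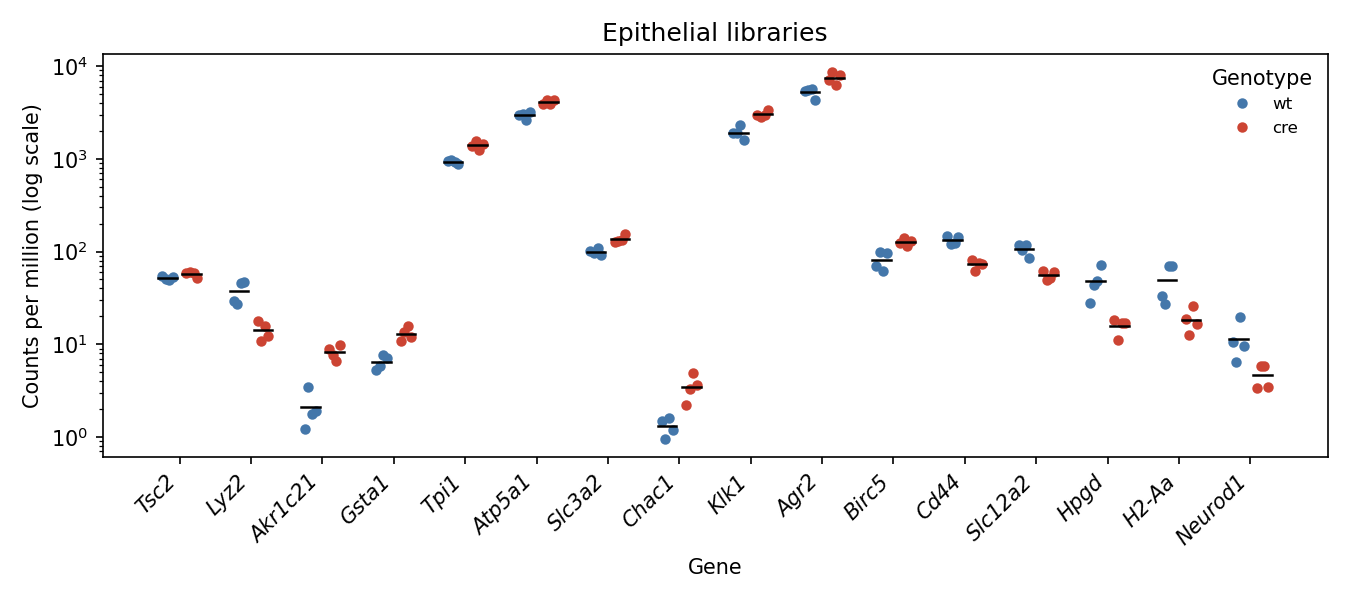
CPM (log axis) of 16 genes in the epithelial libraries; each point is 1 library (4 wt in blue, 4 cre in red) and each bar a group mean. Lyz2 averaged 37.4 CPM in wt and 14.2 CPM in cre, and Tsc2 52.0 and 57.5 CPM.

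Of 51 genes of oxidative phosphorylation 19 rose and 1 fell, and 28 rose and 4 fell adjusted over the list alone. Their median log2 change was 0.27 (camera adjusted p = 1.97e-06; adjusted p = 0.672 with an estimated correlation). Ndufb9, Atp5a1, Ndufa10 and Cox5a rose by 0.52, 0.48, 0.51 and 0.50 on the log2 scale. Of 18 glycolytic genes 11 rose and none fell, and 12 rose and 1 fell adjusted over the list alone (camera adjusted p = 9.29e-06; adjusted p = 0.235 with an estimated correlation). Tpi1 (0.59, SE 0.09), Pgam1 (0.57, SE 0.10), Eno1 (0.54, SE 0.10) and Gapdh (0.47, SE 0.10) were among them. Of 24 genes of the ATF4 and amino acid response 6 rose, and 13 rose adjusted over the list alone (camera adjusted p = 1.65e-05; adjusted p = 0.0976 with an estimated correlation). Slc3a2, an amino acid transporter subunit gene (0.45), the transfer RNA synthetase genes Wars (0.48) and Sars (0.38), and Chac1 (1.42, SE 0.34) rose. Of 37 lysosomal genes 4 rose, and 5 adjusted over the list alone. These included Ctsd (0.52), Atp6v0c (0.53), Ctsb (0.39) and Atp6ap1 (0.41). The list had a camera adjusted p = 0.0222 (adjusted p = 0.415 with an estimated correlation), and 0.0523 with sex in the model and 0.0583 without wt 2.

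Of 24 goblet cell genes Klk1 (0.66) and Agr2 (0.52) rose, and 3 rose adjusted over the list alone. Spink4 (0.49) and Bcas1 (0.52) did not pass. This list had a camera adjusted p = 0.0417 (adjusted p = 0.861 with an estimated correlation). Its call was lost with the GC and length trend removed (0.581), with sex in the model (0.0542) and without cre 9 (0.124), wt 4 (0.169) or wt 7 (0.314). Of 39 mitotic and S phase genes Birc5 (0.63), Stmn1 (0.54) and Tyms (0.47) rose and Top2a (-0.58) fell, and 4 rose and 1 fell adjusted over the list alone. The list had a camera adjusted p = 0.0417 (adjusted p = 0.922 with an estimated correlation). Its call was lost without cre 10 (0.183), cre 8 (0.0596), wt 2 (0.0873) or wt 6 (0.870), and without cre 8 and wt 6 together (0.856).

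Genes of colon stem cells and Wnt targets were lower in cre epithelium. Of 19 measured 4 fell, and 6 fell adjusted over the list alone (camera adjusted p = 0.000247; adjusted p = 0.235 with an estimated correlation). Cd44, whose protein the sort gate selected on, fell from 134 ± 13.8 to 73.2 ± 8.67 CPM (SD, n = 4 each; log2 change -0.87, SE 0.12). The ion transporter gene Slc12a2 (-0.93), Rgmb (-0.77) and Cdca7 (-0.66) fell too. Of 9 tuft cell genes Dclk1 fell (-1.17, SE 0.28), and 6 fell adjusted over the list alone (camera adjusted p = 0.000990; adjusted p = 0.672 with an estimated correlation). Trpm5 and Ptgs1 had log2 changes of -0.91 and -1.26. Of 15 tuft cell genes tested between cell types, 9, Ptgs1 among them, were higher in macrophages and 3 in epithelial cells. Of 22 enteroendocrine genes Neurod1 fell (-1.31, SE 0.32), also adjusted over the list alone. Scg3, Chgb and Nts had log2 changes of -0.96, -0.89 and -0.68. That list had a camera adjusted p = 0.0188 (adjusted p = 0.780 with an estimated correlation), and 0.0715 without cre 10, 0.0585 without cre 9 and 0.0654 without wt 6.

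The resident macrophage and MHC class II lists, whose genes were higher in macrophages than in epithelial cells, were lower in cre epithelial libraries by camera with the preset correlation. Of 17 resident macrophage genes 3 fell, and 7 fell adjusted over the list alone, with a median log2 change of -0.95 (camera adjusted p = 0.000312; adjusted p = 0.672 with an estimated correlation). Itgax (-1.83), Tgfbr2 (-0.42) and the complement gene C1qa (-0.71) fell, and Sirpa (-0.97) did not pass. Of 9 MHC class II genes H2-Aa and H2-DMa (-0.89) fell, and 5 fell adjusted over the list alone (camera adjusted p = 0.000850; adjusted p = 0.672 with an estimated correlation). Ctss (-0.64) and H2-DMb2 (-1.25) did not pass. In all 11 of 38 lists passed, 6 higher and 5 lower. With an estimated correlation camera called 0 (4 at an unadjusted p under 0.05), and fry called 5. Other groupings of the 8 libraries gave up to 17 lists.

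The genotype effect differed between the cell types for 115 of 16375 genes. DESeq2 called 535, and edgeR with a block on mouse number 8, all among the 115. The change was more positive in macrophages for 77 and in epithelial cells for 38. With RLE size factors the genes whose genotype effect differs between cell types split 70 and 53, and with log2(FPKM + 1) 133 and 164. The 5 genes with the smallest p were Gpnmb (log2 difference of effects 7.83, SE 0.58, edgeR adjusted p = 4.27e-06), Fabp5 (3.88, SE 0.30), Ctsd (2.27, SE 0.25), Syngr1 (3.41, SE 0.38) and Ttyh2 (2.58, SE 0.30). Ctsd rose in both populations. Gpnmb, Fabp5, Syngr1 and Ttyh2 had epithelial log2 changes of -0.29, 0.29, 0.53 and -0.10 that did not pass. The count was 54 without cre epithelial 5, 59 without cre epithelial 9, 70 without cre epithelial 10, 74 without wt epithelial 2, 65 without cre macrophage 10, 75 without wt macrophage 2 and 229 without wt macrophage 6.

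**Figure D3:**
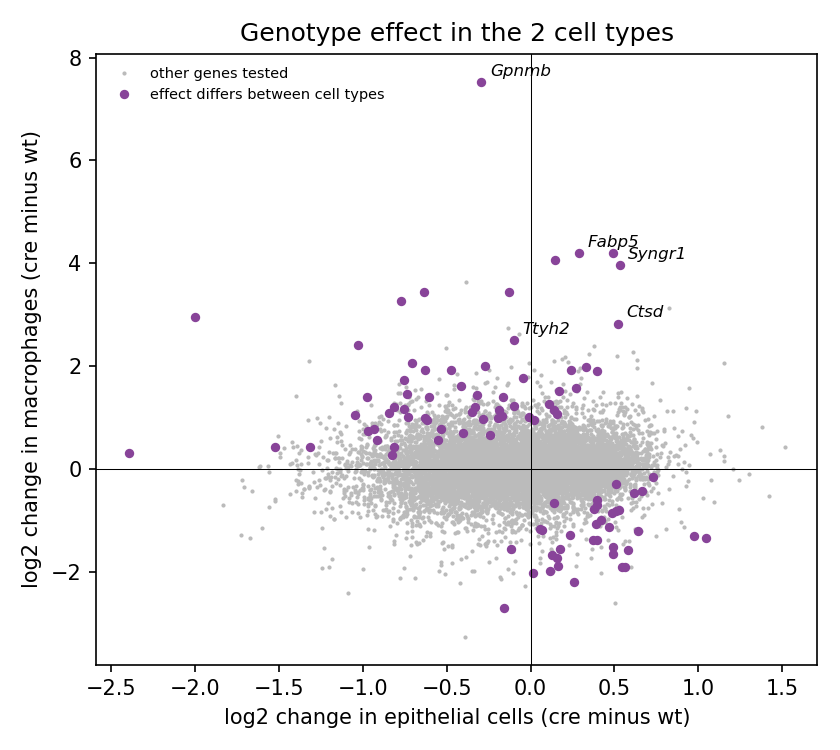
Log2 change (cre minus wt) in macrophages against epithelial cells for the 11686 genes tested in both; the 96 purple points are genes whose effect differed between cell types at an adjusted p under 0.05, and grey points are the others. Gpnmb stands at 7.53 in macrophages and -0.29 in epithelial cells.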

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

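The tests on the GC and length trend, abundant macrophage genes, the recombinase allele, markers of other cells, and splits of the macrophage and epithelial libraries for gene counts were chosen only after the result was seen. Among groups of 4 epithelial libraries, 4 of 126 sets of values held 1 library far from the others, where chance gives about 6.3. In cre 8 the ribosomal RNA gene took 26.7% of counts (95% Wilson interval 26.71 to 26.77), against 7.37% (7.36 to 7.39) to 10.6% (10.59 to 10.63) in the other cre libraries. The same library was highest for Cybb, at 4.74 CPM against 2.17 to 2.498, and for Itgax, at 1.54 CPM against 0.471 to 0.600. In cre 9 Nts was lowest, at 14.03 CPM against 21.5 to 22.3.

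Among 122 named genes, the genotype effect differed between cell types for 16. The log2 effect in macrophages exceeded that in epithelial cells by 7.83 for Gpnmb, 4.92 for Rragd, 3.88 for Fabp5, 3.41 for Syngr1, 2.58 for Ttyh2, 2.27 for Ctsd, 1.73 for mt-Rnr1, 1.67 for Slc12a2, 1.49 for Ctsb and 1.13 for Grn. The difference was -2.59 for Vipr2, -2.48 for Fbln1, -2.42 for Tmem45a, -2.32 for Slc27a3, -2.08 for Pde1b and -1.25 for Plac8. Of 100 splits drawn, 1, the real one, called as many as 115 genes. The highest other, 111, was among 8 splits that kept the macrophage groups, and splits that kept neither cell type's groups reached at most 4. Besides 111 and 97, no other split called more than 33 genes, so most of those 8 splits fell far below 115. The count thus rests on the macrophage grouping in part, but not on it alone. The macrophage libraries allow only 10 splits, too few for a share under 0.05, so chance is not excluded for that count.

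The first pattern is the 133 changes in macrophages. Of the 10 splits of the 6 libraries, 1, the real one, gave as many and the highest other gave 2, and 10 splits are too few for a share under 0.05. Sex stays open because only 1 wt male was sequenced: among 58 genes called against the wt females, that male lay nearer the cre mean in 20.7%. Fewer cells of other types in the cre sort may contribute to the falls, although the gate selects on CD45 and CD64: 7 of 8 marker lists had a median below 0, with Col3a1 at 1626 CPM in wt and 638 in cre, and only endothelial and glial genes lay above it, at 0.40. Of the 19 dendritic cell markers measured, 2 stand in another list too. An effect of the Tsc2 deletion stays open beside these: with sex in the model 2 genes passed, as did the lipid handling (camera adjusted p = 9.81e-11) and dendritic cell (9.73e-10) lists with the preset correlation. An estimated correlation was not run with sex in the model. An effect of the Tsc2 deletion cannot be told apart from one of the recombinase or of the altered Lyz2 locus, since every cre animal carried both.

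The second pattern is the 1243 changes in epithelial cells. Of the 35 splits, 1, the real one, gave as many and the highest other gave 0. That share is under 0.05 and argues against chance, provided that each library came from its own animal. A GC and length trend of the form that the splines remove is argued against as the whole cause. With it removed 577 genes passed in the real split, and at most 1 in any other of the 35. A trend of another form is not covered, and the simulated trend was in GC content alone. How much the GC and length trend contributes cannot be told. With it removed 1242 of the genes kept 74.4% of their median log2 size (0.58 before with a median SE of 0.13, 0.43 after). That lies between the bounds set for either, and 824 lost their call. RNA quality may contribute: within genotype 84.9% of the changed genes followed the ribosomal share in the direction needed, but 69.8% without cre 8, so it stays open. Less macrophage RNA in the cre libraries may add to the falls. These include Lyz2 and 7 of the 61 genes below that were abundant in macrophage libraries, Col3a1 among the 7. A response of the epithelium to the genotype of the animals' myeloid cells stays open as well.

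The third pattern is the fall of Lyz2 in cre epithelial libraries, by 1.40 on the log2 scale. A candidate explanation is less macrophage RNA in those libraries, although the gate excludes CD45: 61 genes at 500 CPM or more in macrophages and at least 6 log2 units above epithelial cells had a median epithelial minus macrophage change of -0.69 (SD 1.12). Lyz2 stood at -1.18, within that spread, and 59 of the 61 genes were lower in cre epithelial libraries. The 61 were picked by abundance in macrophage libraries and include genes of other cells, such as Col3a1 and the antibody genes Igkc and Igha. The spread is widened by Gpnmb at -7.83, which rose in cre macrophages and had an epithelial log2 change of -0.29. Gpnmb stood at 12.4 CPM in wt and 2291 CPM in cre macrophages, but at 1.80 and 1.52 CPM in epithelial libraries. Its rise was thus not carried along, which goes against RNA of such macrophages in the cre epithelial libraries. As 1 gene at few counts it does not decide the explanation. A loss of Lyz2 transcript from the recombinase allele, alike in both cell types, would by itself give equal changes. As the only cause it is argued against by a difference of 1.15 (SE 0.28) between the changes, although the edgeR adjusted p over all genes was 0.0685. Together with less macrophage RNA such a loss stays open. Fewer myeloid cells beside the epithelium of cre animals was not tested.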

How the results depend on the processing

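The GC and length trend, the ribosomal share, the rows left out and the 2 libraries left out were chosen after seeing the data. The cause of each change below was not tested, except that leaving out libraries leaves fewer samples, and in males alone the single wt macrophage library is assumed to vary like the others. The genes changed by genotype in macrophages (133) numbered 517 with DESeq2, 299 without a count filter, 238 with voom, 47 without an FPKM filter, 2 with sex as a covariate, 32 in males alone, 374 with all libraries in one fit and 75 without cre 8 and wt 2, the ends of the first principal component. Single left-out libraries gave 29 to 87. The genes changed by genotype in epithelial cells (1243) numbered 1967 with DESeq2, 2382 with voom, 0 by limma without an FPKM filter (3860 at an unadjusted p under 0.05), 5 in males alone, 19 with all libraries in one fit, 577 with the GC and length trend removed, 0 with the ribosomal share as a covariate and 2359 without cre 8 and wt 6, each the highest of its group in ribosomal share. Single left-out libraries gave 178 to 1947. Males alone left 3 cre and 2 wt epithelial libraries. With sex as a covariate 53 named epithelial genes kept their direction and side of the threshold, 2 lost the call and 3 gained it. The genes whose genotype effect differs between cell types (115) numbered 535 with DESeq2, 195 without a count filter, 297 with log2(FPKM + 1), 183 without an FPKM filter and 54 to 229 with single libraries left out. The genes differing between macrophages and epithelial cells numbered 8416 to 11169 in the settings run, and 8459 to 8948 with single libraries left out. Macrophage lists (14) numbered 2 with an estimated correlation, 8 with fry and 9 to 16 with single libraries left out. Epithelial lists (11) numbered 0 (4 at an unadjusted p under 0.05), 5 and 9 to 12. Tsc2 in macrophages turned from -0.14 to 0.31 with sex as a covariate and 0.32 in males alone, gave -0.33 to -0.01 with single libraries left out, and passed in no setting run. Tsc2 in epithelial cells (0.10 to 0.28) and Lyz2 in macrophages (-0.34 to -0.16) kept their sign and passed in none. Lyz2 in epithelial cells did not pass without an FPKM filter (-1.23, adjusted p = 0.0520) or with the ribosomal share (-1.05, adjusted p = 0.162), with adjusted p from 1.30e-12 to 0.0437 otherwise. Over named genes and settings, 1076 macrophage values kept their direction and side of the threshold, 145 lost the call and 86 gained it, against 932, 334 and 39 in epithelial cells. A block on mouse number gave 8 genes for the difference of effects, all 8 among the 115, and 8416 between cell types. The labels do not say that a number marks 1 animal in both cell types. Of 6 shared numbers, alike in sex in 6, 2 pairs correlated over 0.1 (range -0.07 to 0.11) and 2 were highest with their own number, so numbers were not treated as pairs. Low correlation does not show that such libraries came from different animals. The series text states 3 control and 4 cre mice, fewer than the libraries of each genotype. If it is right, some animals gave more than 1 library, most simply 1 of each cell type. The main tests on all 14 libraries treated such libraries as independent. At this depth and with 3 libraries a side, 19.4% of simulated 2-fold changes were recovered in macrophages.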

Other observations

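Removal of the GC and length trend was chosen after seeing the data, and Gdf15 and Igkv3-12 were picked after their values were seen. No other test in this part was chosen only after its result was seen. Among lists linked to mTORC1 in textbooks, lysosome and autophagy passed as higher in macrophages (camera adjusted p = 4.04e-42 and 0.00853), and the ATF4 response, glycolysis and lysosome in epithelial cells (1.65e-05, 9.29e-06 and 0.0222). With an estimated correlation none of these passed (adjusted p = 0.0847 and 0.201 in macrophages, and 0.0976, 0.235 and 0.415 in epithelial cells). The pathway components and the sterol and fatty acid synthesis lists passed in neither population. Nor did the ribosome biogenesis, hypoxia response and pentose phosphate lists. Cytosolic ribosomal protein genes passed as lower in macrophages (camera adjusted p = 0.0167, and 0.897 with an estimated correlation). Components of the mTORC1 pathway had a median log2 change of 0.04 over 37 genes in macrophages (camera adjusted p = 0.108) and -0.09 over 36 in epithelial cells (adjusted p = 0.796). Sterol synthesis genes had medians of -0.03 and -0.05, and fatty acid synthesis genes of -0.03 and -0.11. Glycolytic genes did not pass in macrophages, with a median of 0.02 (adjusted p = 0.834). Gdf15, a stress-induced cytokine gene, rose from 96.5 ± 27.4 to 419 ± 71.4 CPM in cre macrophages (SD, n = 3 each; log2 change 2.12, SE 0.23, edgeR adjusted p = 0.00555). The 133 macrophage genes include 8 antibody variable segments, such as Igkv3-12 at 0.403 CPM in wt and 119 in cre. Segments share sequence, so their counts are uncertain.

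The other lists did not pass in macrophages, with all 30 adjusted p between 0.0694 and 0.960. Metabolic and stress lists had median log2 changes of 0.15 for oxidative stress response (3 of 20 rose), -0.22 for hypoxia response, -0.06 for ATF4 and amino acid response, 0.09 for dissociation stress, 0.05 for oxidative phosphorylation and -0.07 for unfolded protein response. Medians were -0.01 for ribosome biogenesis and translation factors, 0.01 for p53 and arrest, -0.09 for the tricarboxylic acid cycle, -0.03 for pentose phosphate and nucleotide synthesis and -0.0014 for mitotic and S phase genes. Immune lists stood at 0.20 for toll-like receptors and bacterial sensing, -0.30 for alternative activation, -0.12 for MHC class I, -0.49 for neutrophil, and -0.20 for B and plasma cell. Epithelial and vascular lists stood at -0.23 for tight junction and adhesion, -0.33 for tuft cell, -0.15 for colon stem cell, -0.48 for absorptive colonocyte, -0.33 for pan-epithelial, -0.12 for epithelial growth factors, 0.77 for Paneth, -0.01 for goblet, 0.01 for epithelial defence and 0.40 for endothelial and glial genes. Median, mean and test differed in sign for endothelial and glial, epithelial defence and pentose phosphate genes.

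In epithelial cells 27 lists did not pass, with adjusted p between 0.0858 and 0.934. Metabolic and stress lists had median log2 changes of 0.10 for the tricarboxylic acid cycle, 0.15 for oxidative stress response, 0.15 for pentose phosphate and nucleotide synthesis, -0.10 for dissociation stress, -0.01 for unfolded protein response, -0.05 for autophagy, -0.0024 for p53 and arrest, 0.01 for ribosome biogenesis, and -0.12 for hypoxia response. Epithelial lists stood at 0.06 for epithelial defence, -0.39 for epithelial growth factors, 0.13 for pan-epithelial, -0.12 for tight junction and adhesion, -0.11 for absorptive colonocyte and -0.07 for Paneth genes. Immune lists stood at -0.16 for monocyte, -0.26 for macrophage growth factors, -0.12 for toll-like receptors, -0.25 for inflammatory cytokines, 0.05 for MHC class I, -0.15 for lipid handling, -0.23 for interferon response and 0.07 for dendritic cell. Median, mean and test differed in sign for absorptive colonocyte, unfolded protein response, sterol synthesis, Paneth, hypoxia and dendritic cell genes. Cytosolic ribosomal protein genes had a median of -0.02 (adjusted p = 0.549), and passed as lower by camera with the preset correlation and the GC and length trend removed (adjusted p = 9.50e-06), as did macrophage growth factors (0.0266). An estimated correlation was not run with the trend removed, and without its removal gave 0.922 and 0.861.

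Sequence of another strain may be carried along with the recombinase allele and change the counts of genes beside Lyz2. Among neighbours fixed in advance, 0 of 15 changed in macrophages and 0 of 14 in epithelial cells by edgeR (Fisher's exact two-sided p = 1 and 0.632). The upper 95% Clopper-Pearson bounds of 21.8% and 23.2% are too wide to exclude an excess over the 0.944% and 9.17% of all genes tested.

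In epithelial cells 12 of the 35 splits gave at least the real 11 lists and another split gave 17, so chance is not excluded for that count. In macrophages 2 of the 10 splits gave at least the real 14 lists and the highest other gave 17, and 10 splits are too few for a share under 0.05. Between cell types 1 of 100 splits drawn, the real one, reached 8543 genes and the highest other 5661, so chance is excluded for that count.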
